A study of Oryza sativa with 9 samples.

How the data were processed

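Small RNA of rice (Oryza sativa, cultivar Pusa basmati) was measured by sequencing in 9 libraries. Per the labels, plants were kept at 28 ± 2 °C and 70% humidity with 16 h of light and 8 h of dark. Salt-treated seedlings received 200 mM NaCl. Libraries were made per the labels from 1 ug of total RNA, with a gel step that kept 15 to 30 nt. The deposited files each list distinct sequences with a count, the whole number of reads of that sequence, as the values themselves show. Identical reads had been collapsed and read lengths vary, so a 3′ adapter appears to have been removed before deposit. The tools, versions and filters the authors used are not given in the sources used here. No genome was used, so sequences were given no position, and reads from another organism could not be told from rice reads by mapping. For that reason single sequences are described by length and level and are not printed.

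Groups follow the labels. Control leaf has 3 libraries, called replicates 1 to 3, and each of the other 6 groups has 1. The labels do not say whether the 3 control leaf libraries come from separate plants. The p-values therefore measure only the spread between these samples, which may be technical. Total reads ranged from 4642464 to 24083792 per library and reads of 18 to 26 nt from 3932999 to 21034839. A count of 0 allows up to 3 counts, which is 0.145 RPM (reads-per-million) of the 18 to 26 nt reads in the Gly control library and 0.763 in control root. Intervals and such floors cover counting error only, since reads are not independent molecules. The floor was 3 counts in a lone library at 0, or 3 counts over the 3 control leaf libraries together where all of them were at 0.

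A total of 97 mature sequences of 41 miRNA families, tasiR-ARF included, was listed from general knowledge before the data were examined. The tests, the lists of families, the rule for naming families and most alternatives were also fixed before the data were examined. A read of 18 to 26 nt was counted for a family when it held positions 2 to 18 of a listed mature sequence with no mismatch and started within 2 nt of the mature start. Closely related members and precursors of a family share such reads, so values are for families and cannot be assigned to loci. Families with at least 10 reads in 2 libraries or 50 reads in 1 were tested. This left 40 families, and miR437 was not tested.

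Counts were scaled by TMM over the families and tested with edgeR's quasi-likelihood test, with 1 coefficient per group over all 9 libraries. P-values are 2-sided and Benjamini-Hochberg adjusted over the families tested, with a threshold of 0.05. The residual spread came only from the control leaf libraries, so each lone library is assumed to vary like them. The biological coefficient of variation was 0.253. Log2 fold changes are given with the standard error (SE), taken as the fold change divided by the square root of the test statistic. Where 1 library was compared with 1 library no test was made. The ratio of TMM-scaled RPM, the scale of all family values, is given with its exact conditional (Clopper-Pearson) 95% interval. A family was counted where the ratio was at least 2-fold, the interval excluded 1 and at least 1 library reached 10 RPM. Single sequences of 18 to 26 nt with at least 20 reads in at least 1 library were tested in the same way, those of the listed families included. Their TMM factors came from these sequences and not from the families. Sequences after the end of the shortened file were kept out of this test. The difference between the salt effects in Gly leaf and in leaf was tested as an interaction term in the same edgeR fit, a test added after the data were seen.

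Lists of families were fixed for 9 themes. They are salt (families reported under salt in plants), auxin, phase change and flowering, leaf and meristem development, nutrient, copper and laccase, small RNA machinery, reproductive phasiRNA triggers, and rice or monocot families. The lists hold 37 families, and miR437 is the 1 of them that was not tested. Each list's median log2 value was set as a percentile among 10000 random lists of the same size. Each member was drawn from itself and the 10 families nearest in level. For most comparisons mainly the extreme percentiles are printed, so they look rarer than they are. Such a percentile describes these libraries only. The families named are, per comparison, up to 12 with the largest rise and up to 12 with the largest fall past the test or the size rule. Up to 4 members of each list with the highest mean level are named as examples. Up to 3 single sequences per direction outside the listed families are described. Families outside this rule are named only as members of a list or of a count, and were chosen after their values were seen.

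Listed animal and dicot miRNA sequences, 12 in all, were counted as RPM of the 18 to 26 nt reads without further scaling. The file of control leaf replicate 2 ends within the sequences that begin with TTTCAT. The other control leaf libraries hold 0.595% and 0.629% of their reads from there on. For miR159 this concerned 1 of 5 listed forms and for miR2275 it concerned 2 of 3. Values of these 2 families use the other 2 control leaf libraries. Chi-square tests of sequences with at least 50 reads, without error and adapter forms, gave 1.52, 1.48 and 2.37 per degree of freedom for the 3 pairs of control leaf libraries. Each pair differed by more than sampling, so the libraries were not merged. Repeat preparations or runs of 1 sample would also differ in this way, so the test does not show separate plants.

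The alternatives were DESeq2 size factors, no normalization factor, DESeq2's Wald test, no filter, exact mature sequences, a window of 20 to 24 nt, single-read sequences left out, only the 4 libraries compared, and each control leaf library left out in turn. For comparisons of 1 library with 1 library, a size of 4-fold and a minimum of 100 RPM were tried. Further alternatives were chosen after the data were seen. They are scaling without miR156, a fit without the library labelled salt root, control leaf libraries summed, and control leaf replicate 2 alone. Where the text speaks of 4 scalings, these are TMM, DESeq2 size factors, no normalization factor and TMM without miR156. The scale of the sequence test was not among them.

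The scripts' tests were tested on simulated data made from the real libraries' levels. In the family test with 40 families, a 4-fold change was recovered in 72.5% of cases for salt leaf, 85.0% for Gly control, 77.5% for control root and 82.5% for flower. For a 2-fold change these shares were 11.2%, 12.5%, 15.0% and 15.0%. Among unchanged families at most 2.19% were called in any of these comparisons. All simulated families had the same common spread, a coefficient of variation of 0.253, and few were changed. Most real families with at least 50 reads varied less. Their median absolute log2 ratio was 0.0859, 0.0797 and 0.108 between the pairs of control leaf libraries. The shares recovered in simulation therefore do not hold for such families. In the real data 24 to 34 of 40 families passed, so these shares do not give the error rate of the real calls. Each simulated lone library also had that spread, so false calls from a spread that is only technical could not show. In the sequence test with 22664 sequences and 200 changed, a 4-fold change was recovered in 55.5%, 69.5%, 59.5% and 50.0% for the same comparisons. For a 2-fold change the share was 30.5% for Gly control and 0% for the other 3 comparisons. The 95% interval of a ratio covered the true ratio in 96.2% of simulated cases. The tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.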

Results

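Small RNA was sequenced from leaf, root and flower of the rice cultivar Pusa basmati, in a series that compares small RNA of salt-tolerant and salt-sensitive rice. The 9 libraries form 7 groups. All plants are labelled susceptible. Control leaf has 3 libraries. Salt leaf, control root, flower taken before pollination, and a library labelled salt root have 1 library each. Lines that over-express glyoxalase, an enzyme that removes the toxic metabolite methylglyoxal, gave 1 leaf library without salt and 1 with salt, called Gly control and Gly salt. Control leaf replicates 1 to 3 had 6027458, 5482642 and 5917347 reads in total, salt leaf had 4642464 and control root 5490031. Flower had 6973783 reads, Gly control 23056584, Gly salt 22519301 and the library labelled salt root 24083792. Groups other than control leaf have no replicate.

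The 21-nt class, the usual length of plant miRNAs, was largest in control leaf, and the 24-nt class, the usual length of siRNAs that guide DNA methylation, was largest in flower. Of the reads of 18 to 26 nt, 47.6% ± 0.126 (SD, n = 3) were 21 nt long in control leaf, against 28.8% in salt leaf (Wilson 95% interval 28.7 to 28.8). The share was 29.1% in Gly control, 29.6% in Gly salt, 21.9% in control root and 15.3% in flower. Reads of 24 nt made up 14.1% ± 0.057 (SD, n = 3) in control leaf, 22.7% in salt leaf, 20.7% in Gly control, 24.4% in Gly salt, 15.4% in control root and 59.6% in flower. All of these differences from control leaf exceeded the range of its libraries, 47.5 to 47.7% for 21 nt and 14.1 to 14.2% for 24 nt. The listed miRNA families took 58.5% ± 0.0813 (SD, n = 3) of the reads in control leaf, 33.7% in salt leaf, 31.2% in Gly control, 31.3% in Gly salt, 18.3% in control root and 6.13% in flower. With these families left out, the 21-nt share was 26.2% in control leaf, 16.0% in salt leaf, 14.2% in Gly control and 11.2% in flower. The 24-nt share was then 33.9% in control leaf, 34.2% in salt leaf, 35.1% in Gly salt and 63.5% in flower, but 29.7% in Gly control and 18.8% in control root, both below control leaf. Most of the higher 24-nt share in salt leaf thus went with its smaller share of miRNA reads.

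**Figure D1:**
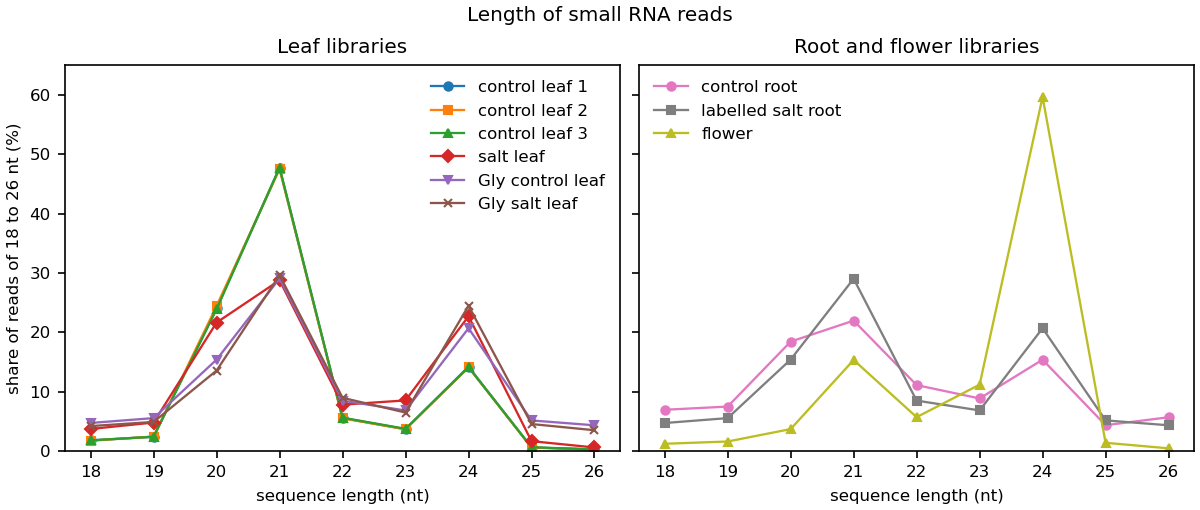
Share of reads of 18 to 26 nt (vertical axis, percent) at each length (horizontal axis, nt), in leaf libraries on one panel and in root and flower libraries on the other. Control leaf peaks at 21 nt with 47.6% of reads and flower at 24 nt with 59.6%.

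The library labelled salt root held every one of the 3259596 distinct sequences of Gly control. Of the sequences read once in Gly control, 100% were also listed there, while no other pair of libraries shared more than 17.97%. Counts were equal for 97.7% of the shared sequences and lower for 0 of them. The remaining 1027208 reads made up 4.27% of the library labelled salt root, and 46.5% of them were shorter than 17 nt. This library can therefore not be read as independent of Gly control.

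**Figure D2:**
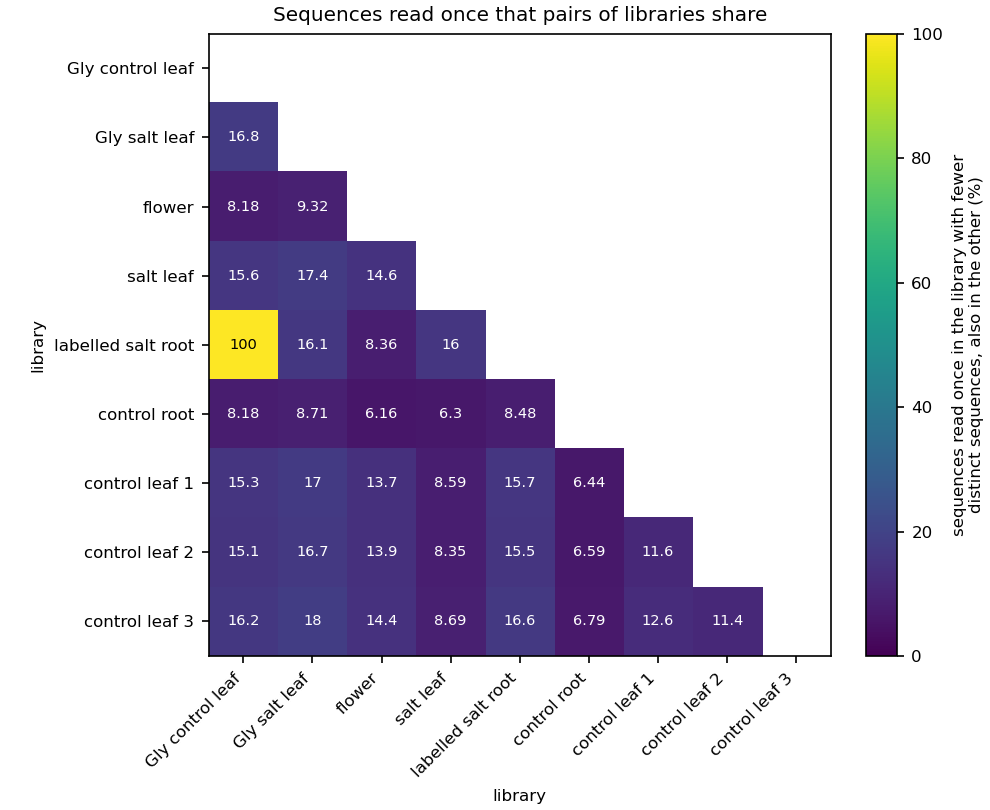
Heat map of the percentage of sequences read once in the library with fewer distinct sequences that the other library also lists, for each pair of the 9 libraries on both axes. The pair of Gly control and the library labelled salt root stands at 100%, and no other pair exceeds 17.97%.

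The comparison of salt leaf with control leaf asks which miRNA families differ in leaf under salt. The longest reads were 27 nt in salt leaf and 33 or 35 nt in the control leaf libraries, so salt and read length differ together here. miR529, which targets SPL transcription factors, rose by 3.92 ± 0.10 on the log2 scale (SE), from 26.7 ± 2.18 RPM in control leaf (mean ± SD, n = 3) to 405 RPM. miR444, which targets MADS-box genes, fell by 4.10 ± 0.12, from 2165 ± 150 to 127 RPM. miR396, which targets growth-regulating factors, fell by 2.64 ± 0.06, from 2544 ± 21.4 to 409 RPM. miR390, which starts production of tasiR-ARF, rose by 1.84 ± 0.12, while tasiR-ARF, which targets auxin response factors, fell by 1.77 ± 0.08. Adjusted p by edgeR was 1.23e-05 for miR529, 1.23e-05 for miR444 and 9.31e-06 for miR396.

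Of the 40 families tested by edgeR, 24 passed in salt leaf, of which 11 rose and 13 fell. Families that rose under all 4 scalings were miR529, miR390, miR827, which targets phosphate transporters with an SPX domain (1.79 ± 0.10), miR1868 (1.41 ± 0.16) and miR169, which targets NF-YA factors (1.21 ± 0.12). Families that fell under all 4 scalings were miR444, miR396, tasiR-ARF, miR394 (by 1.98 ± 0.19), miR1861, miR162 (-1.60), miR1862 (-1.40), miR172 (-1.27), miR408 (-0.99) and miR530. miR530 had 0 reads in salt leaf, at least 3.29-fold lower than the 3.81 ± 1.34 RPM of control leaf at the floor of 3 counts. The 95% interval against the summed control leaf libraries allows as little as 2.63-fold. miR1861 had 3 reads in salt leaf, a ratio of 0.256 (95% interval 0.0518 to 0.776) to the summed control leaf libraries. miR156, the most abundant family, which targets SPL factors, did not pass (0.05 ± 0.08), with a value of -0.82 without a normalization factor. On the TMM scale it stood at 503445 RPM in salt leaf and 486933 ± 23622 in control leaf, which are not shares of reads. Of the reads in the length range counted, miR156 took 1303971 of 4372916 in salt leaf and 2976129 of 5644104 in control leaf replicate 1. TMM factors were 0.592 in salt leaf and 1.04 to 1.13 in control leaf, so the near equal levels rest on the scaling.

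In the salt list, 3 of 14 families rose, 5 fell and 6 did not pass, and 8 passed when adjusted over the list alone by edgeR. Its members miR390, miR169 and miR164, which targets NAC factors (0.69 ± 0.06), rose, and miR394, miR396, miR408, miR820 (-0.49) and miR167 (-0.40) fell. The value of miR164 turned to -0.18 without a normalization factor, and that of miR167 to 0.69 with exact mature sequences. Of the 5 auxin families, 1 rose, 2 fell and 2 did not pass (3 adjusted over the list alone). Of the 4 phase change families, miR529 and miR535 (0.53) rose and miR172, which targets AP2-like factors, fell (3 adjusted over the list alone), though miR535 turned to -0.34 without a normalization factor. In leaf and meristem development, 3 of 6 rose and 2 fell (5 adjusted over the list alone). The risen members miR164, miR166 (0.47) and miR171 (0.48) each turned negative without a normalization factor, while miR396 and miR159 (-0.44) fell. Of the 5 nutrient families, miR827 and miR169 rose and miR444 fell (3 adjusted over the list alone). Of the 4 copper and laccase families, miR408, which targets plantacyanins, fell (1 adjusted over the list alone). miR528, which targets ascorbate oxidase (-0.17 ± 0.06), miR397, which targets laccases (-1.07 ± 0.40), and miR398, which targets copper/zinc superoxide dismutase (-0.99 ± 0.52), did not pass. In the machinery list, miR168, which targets ARGONAUTE, rose by 0.69, a value of -0.18 without a normalization factor, and miR162, which targets DICER-LIKE, fell (2 adjusted over the list alone). Neither of the reproductive triggers miR2118 and miR2275 passed, at 1 read each in salt leaf. The count by edgeR was 0 at an unadjusted p under 0.05, and 0 adjusted over the list alone. Of the 9 rice or monocot families measured, 0 rose, 5 fell and 4 did not pass (5 adjusted over the list alone). The medians of the lists in salt leaf lay between percentiles 13.9 and 94.9 of random lists.

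The split of 11 rises and 13 falls in salt leaf was 13 and 10 with DESeq2 size factors and 5 and 23 without a normalization factor. The median log2 value of all families was -0.18 with TMM, 0.08 with DESeq2 size factors, -1.06 without a factor and -0.15 without miR156. Scaled over single sequences, 198 reads in salt leaf came to 39.7 RPM and 833 in control leaf to a mean of 73.8. On the family scale, 113 reads in salt leaf came to 43.6 RPM and 1400 in control leaf to 79.1. Rises in salt leaf would thus be smaller on the sequence scale, and falls larger. That scale was not tried for the families. Left out in turn, control leaf replicate 2 ended the edgeR calls of miR530 (adjusted p 0.0712), miR1878 (0.0515) and miR171 (0.0569), replicate 1 that of miR171 (0.0912) and replicate 3 that of miR1861 (0.0720). With exact mature sequences the call of miR530 also ended (adjusted p 0.630 by edgeR). Of the 9 families that passed and fell at least 2-fold in salt leaf, 6 also fell in Gly control without salt under all 4 scalings, namely miR172, miR394, miR396, miR444, miR1861 and tasiR-ARF.

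The comparison of Gly control with control leaf addresses the effect of glyoxalase over-expression without salt. The sequences of Gly control are also listed under the label salt root, and the values below hold for Gly leaf only if the label Gly control is the right one. All 4 copper and laccase families were higher in the Gly line. miR398 rose by 4.59 ± 0.28 on the log2 scale, from 3.05 ± 0.846 RPM in control leaf (SD, n = 3) to 74.2 RPM. miR408 rose by 2.87 ± 0.10, from 61.4 ± 4.70 to 450 RPM, miR528 by 1.79 ± 0.06, from 5456 ± 211 to 18870 RPM, and miR397 by 1.01 ± 0.28, a call that did not hold under every scaling. miR156 fell by 2.14 ± 0.09, from 486933 ± 23622 to 110540 RPM, and miR396 by 2.02 ± 0.05, to 626 RPM. Adjusted p by edgeR was 0.000115 for miR398, 2.49e-05 for miR408, 2.49e-05 for miR528 and 3.29e-05 for miR156.

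Of the 40 families, 34 passed by edgeR in Gly control, of which 16 rose and 18 fell, and 25 did so under all 4 scalings. Among those 25, the further rises were miR530 (3.28 ± 0.34), miR2118, miR399, which acts in phosphate supply (2.498 ± 0.39), miR160, which targets auxin response factors (2.44 ± 0.15), and miR166, which targets HD-ZIP III factors (1.40 ± 0.05). miR1425, which targets PPR proteins, miR171, miR167 and miR1868 rose by 1.11, 1.11, 1.08 and 1.00. miR2118 had 33 reads in Gly control and 2 in the summed control leaf libraries, a ratio of 8.53 (95% interval 2.18 to 73.4). Among the falls under all 4 scalings were miR1861 (by 3.66 ± 0.36), miR395, which acts in sulfate assimilation (by 2.64 ± 0.46), miR169 (-1.86), miR393, which targets auxin receptors (-1.74), and miR1870 (-1.48). miR394, tasiR-ARF, miR444 and miR1432 followed with -1.33, -1.32, -1.28 and -1.09, then miR827 and miR172 with -0.97 and -0.92.

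The copper and laccase list rose in 4 of 4 families (4 adjusted over the list alone by edgeR), with a median of 2.33 at percentile 99.3 of random lists. Of the 5 nutrient families, miR399 rose and miR395, miR169, miR444 and miR827 fell (5 adjusted over the list alone), with a median of -1.28 at percentile 8.90. In the salt list, 6 of 14 rose and 6 fell (12 adjusted over the list alone), and in auxin 2 of 5 rose and 3 fell (5 adjusted over the list alone). In phase change, miR535 (0.47) rose, with a value of -0.08 when scaled without miR156, and miR156, miR529 (-0.61) and miR172 fell (4 adjusted over the list alone). The fall of miR529 came to 0.01 without a normalization factor. In leaf and meristem development miR166 and miR171 rose and miR396 and miR159 (-0.79) fell (4 adjusted over the list alone). Of the machinery families, miR162 fell (-0.74) and miR168 did not pass (1 adjusted over the list alone). Of the reproductive triggers, miR2118 rose and miR2275 did not pass (1 adjusted over the list alone). Of 9 rice or monocot families, 5 rose and 3 fell (9 adjusted over the list alone), and miR820 (0.73), which targets a DNA methyltransferase, stood at -1.17 with exact mature sequences.

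The split of 16 rises and 18 falls in Gly control was 19 and 13 without a normalization factor and 12 and 21 when scaled without miR156. The median log2 value was -0.54 with TMM, -0.26 with DESeq2 size factors, 0.07 without a factor and -1.10 without miR156. Without control leaf replicate 3 the edgeR calls of miR2118 (adjusted p 0.0885) and miR1878 (0.0579) ended, and without replicate 1 that of miR535 (0.0561). That of miR530 ended with exact mature sequences (0.125 by edgeR). The longest reads were 28 nt in both Gly libraries, 27 nt in salt leaf and 33 or 35 nt in the control leaf libraries, so these groups cannot be told apart from the read length of their libraries.

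The comparison of Gly salt with Gly control asks what salt changed in leaf of the Gly lines, and it too rests on the label of Gly control being right. None of the 40 families differed past the 2-fold size rule, a comparison of 1 library with 1 library and without a test. miR827 had the highest ratio among the 32 families with at least 10 RPM, 1.80 (95% interval 1.69 to 1.93), followed by miR397 with 1.75 (1.59 to 1.93). miR528 stood at 29465 RPM in Gly salt and 18870 in Gly control, a ratio of 1.56. The lowest ratio was that of miR535, 0.740 (0.723 to 0.758), and miR156 had 0.899. The interval lay above 1 in 24 of these families, below 1 in 6 and held 1 in 2. The median ratio of all families was 1.19.

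With reads of 20 to 24 nt only, 2 families passed the size rule in Gly salt, miR827 with a log2 ratio of 1.08 and miR397 with 1.05. In every list 0 members were higher and 0 lower past the size rule. The median log2 ratio was 0.25 for salt, 0.45 for auxin, 0.02 for phase change, 0.20 for leaf and meristem development and 0.40 for nutrient. It was 0.34 for copper and laccase, 0.17 for machinery, 0.15 for the reproductive triggers and 0.33 for rice or monocot families. These medians lay between percentiles 7.39 and 80.1 of random lists.

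The comparison of Gly salt with salt leaf sets the Gly line beside the non-Gly line under salt. All 4 copper and laccase families were higher in Gly salt. miR398 had 75.6 RPM in Gly salt against 4 reads in salt leaf, a ratio of 49.0 (95% interval 19.1 to 180). The ratio was 13.3 (10.7 to 16.8) for miR408, 7.44 (4.24 to 14.4) for miR397 and 6.08 (5.98 to 6.19) for miR528. miR529 was lower, with 20.9 RPM against 405, a ratio of 0.0517 (0.0469 to 0.0569), and miR156 had a ratio of 0.197. The miR156 difference fell short of 2-fold without a normalization factor.

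Of the 40 families, 12 were higher and 7 lower in Gly salt than in salt leaf past the size rule. Besides those named, miR530 was at least 40.5-fold higher, with 0 reads in salt leaf. miR444 had a ratio of 7.73, miR1862 6.97, miR160 5.45, miR1425 4.15, miR167 4.06, miR162 2.68 and miR820 2.25. The lower families were miR169 (0.150), miR390 (0.220), miR827 (0.265), miR393 (0.359) and miR1870 (0.474), besides miR529 and miR156. The split was 11 higher and 9 lower with DESeq2 size factors and 22 higher and 2 lower without a factor. Most of the 7 lower calls thus ended without a factor, where miR393 and miR1870 turned to log2 ratios of 0.00 and 0.40. miR156 had 3384337 of 20593657 reads in Gly salt and 1303971 of 4372916 in salt leaf, less than 2-fold apart as shares.

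The copper and laccase list had 4 of 4 higher, with a median log2 ratio of 3.31 at percentile 98.3 of random lists. Of 9 rice or monocot families, 6 were higher and 3 neither (median 2.05, percentile 97.4). In the salt list, 6 of 14 were higher and 4 lower. In auxin, miR160 and miR167 were higher and miR390 and miR393 lower. In phase change, miR156 and miR529 were lower (median -1.42, percentile 1.73), though miR156 not by 2-fold without a normalization factor. In nutrient, miR444 was higher and miR169 and miR827 lower (median -1.58, percentile 4.92). In the machinery list miR162 was higher. Neither the 6 leaf and meristem families nor the 2 reproductive triggers held a member past the size rule.

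**Figure D3:**
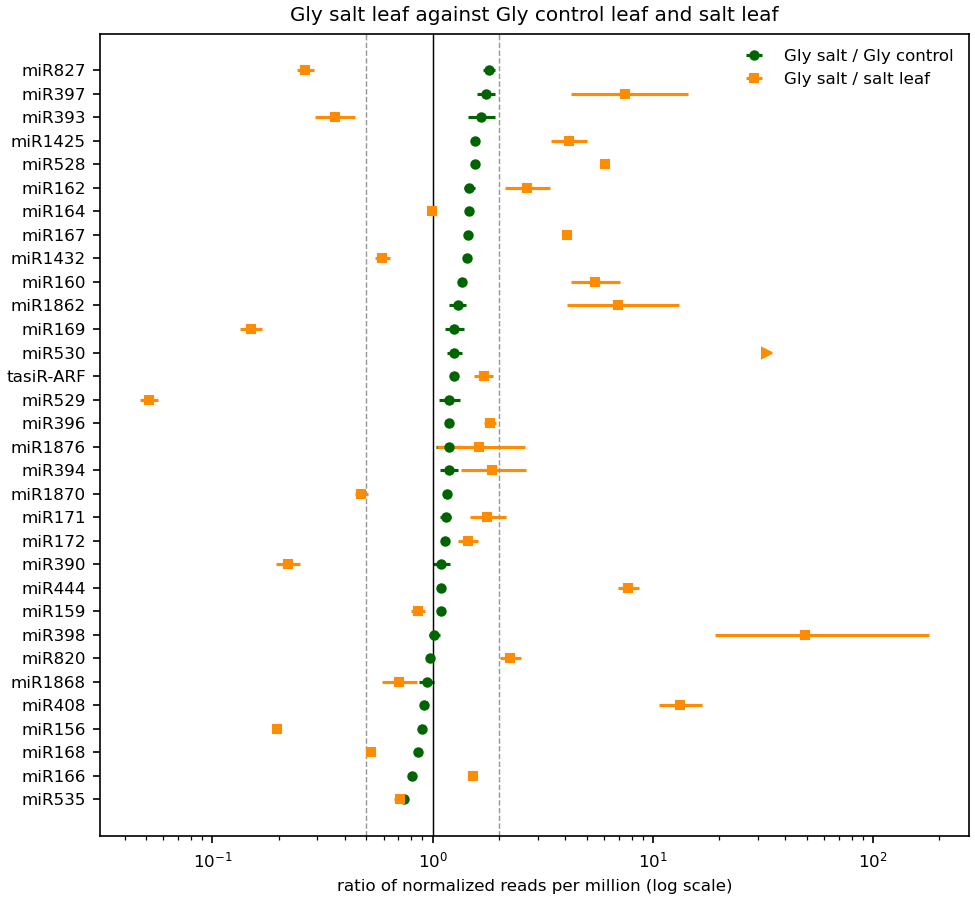
Ratio of normalized RPM (horizontal axis, log scale) of Gly salt to Gly control (green circles) and of Gly salt to salt leaf (orange squares) for the 32 families with at least 10 RPM, with 95% counting intervals as bars, lower bounds as triangles and 2-fold marked by dashed lines. Every circle lies between 0.740 and 1.80, while the squares run from 0.0517 for miR529 to 49.0 for miR398.

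The salt effect itself was compared between the lines by an interaction term in edgeR, chosen after the data were seen. It passed for 23 of 40 families, 15 with a higher value in the Gly line and 8 with a lower one. Of the 4 groups in this term 3 have 1 library, Gly salt and Gly control among them, so its p-values rest on the spread of the control leaf libraries alone, which may be technical. For miR444 the salt effect was higher in the Gly line by 4.23 ± 0.15 on the log2 scale, and for miR396 by 2.89 ± 0.08. For miR529 the difference was -3.67 ± 0.18 and for miR390 it was -1.71 ± 0.20. The split of 15 and 8 was 8 and 11 with DESeq2 size factors, 23 and 3 without a factor and 11 and 10 without miR156, and 21 of the 23 families kept their sign under all 4 scalings. The interaction uses Gly control, so it too holds only if the label of that library is right. Read length differed between salt leaf and control leaf but not between the Gly libraries, with longest reads of 28 nt in both. As miR172, miR394, miR396, miR444 and tasiR-ARF also fell in Gly control without salt, the term cannot be read as a difference in salt effect alone.

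The comparison of control root with control leaf asks for the tissue difference without salt. Only 71.6% of the reads of control root fell in the length range counted, against 87.3 to 94.2% in the other libraries. The share with an undetermined base (N) was 1.28% in control root and at most 0.340% in the others. Tissue cannot be told apart from library quality here, since control root has no replicate. miR160, which targets auxin response factors, rose by 4.45 ± 0.15 on the log2 scale in root, from 17.6 ± 2.09 RPM in control leaf (SD, n = 3) to 385 RPM. miR166, which targets HD-ZIP III factors, rose by 2.40 ± 0.05, from 4455 ± 113 to 23430 RPM, and miR1425 by 3.30 ± 0.13, from 55.7 ± 5.89 to 548 RPM. miR528, which targets ascorbate oxidase, fell by 5.30 ± 0.08, from 5456 ± 211 to 138 RPM. miR396, which targets growth-regulating factors, fell by 2.96 ± 0.06, and miR156 by 1.54 ± 0.09. Adjusted p by edgeR was 1.89e-05 for miR160, 2.01e-06 for miR166 and 2.01e-06 for miR528.

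Of the 40 families, 31 passed by edgeR in root, of which 16 rose and 15 fell. Under all 4 scalings 28 of them passed the same way. Further rises among these were miR319, which targets TCP factors (3.45 ± 0.77, 31 reads in root), miR171 (2.17), miR1878 (2.13), miR397 (2.12), miR1861 (2.09), miR1876 (1.45), miR535 (1.33), miR827 (1.12), miR1432 (0.94) and miR390 (0.90). Further falls were miR394 (-2.21), miR444 (-2.19), miR408 (-2.12), miR159 (-1.28), miR169 (-1.18), miR1862 (-0.98), miR1870 (-0.88), miR162 (-0.71), miR172 (-0.70), tasiR-ARF (-0.51) and miR530. miR398 had 0 reads in root, at least 3.17-fold lower than in control leaf at the floor of 3 counts. The 95% interval against the summed control leaf libraries allows as little as 2.54-fold. miR530 had 2 reads, a ratio of 0.167 (95% interval 0.0198 to 0.627) to the summed control leaf libraries.

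In leaf and meristem development, miR166, miR171, miR319 and miR164 (0.63) rose and miR396 and miR159 fell (6 adjusted over the list alone by edgeR), with a median of 1.40 at percentile 98.3 of random lists. In copper and laccase, miR397 rose and miR398, miR408 and miR528 fell (4 adjusted over the list alone), with a median of -1.89 at percentile 2.58 when miR398 is set to its bound. In the salt list, 5 of 14 rose and 7 fell (12 adjusted over the list alone). In auxin, miR160 and miR390 rose and tasiR-ARF fell (3 adjusted over the list alone). In phase change, miR535 rose and miR156 and miR172 fell (3 adjusted over the list alone). In nutrient, miR827 rose and miR169 and miR444 fell (3 adjusted over the list alone). In the machinery list miR162 fell (1 adjusted over the list alone). Neither miR2118 nor miR2275 passed, with 2 and 3 reads in root (0 adjusted over the list alone by edgeR and 0 at an unadjusted p under 0.05). Of 9 rice or monocot families, 5 rose and 4 fell (9 adjusted over the list alone).

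The median log2 value in root was 0.32 with TMM, 0.04 with DESeq2 size factors, -0.14 without a factor and 0.28 without miR156. Without control leaf replicate 2 the edgeR calls of miR530 (adjusted p 0.103) and miR1862 (0.0639) ended. With exact mature sequences that of miR530 ended as well (0.609 by edgeR). Against control leaf replicate 2 alone, which shares the longest read of 35 nt with root, 10 families were higher and 8 lower past the 2-fold size rule. Sequences of listed animal miRNAs reached 196 RPM in control root, against 33.5 ± 4.38 in control leaf (SD, n = 3).

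The comparison of flower with control leaf covers the reproductive tissue. miR2275, which triggers 24-nt phased siRNAs in anthers, rose by 9.37 ± 0.20 on the log2 scale, with 389 reads in flower and 3 in the summed control leaf libraries used for it, a ratio of 682 (95% interval 232 to 3321). miR2118, which triggers 21-nt phased siRNAs in reproductive tissue, rose by 5.39 ± 0.78, with 12 reads against 2, a ratio of 44.9 (10.0005 to 413). miR529, which targets SPL factors, rose by 5.79 ± 0.11, from 26.7 ± 2.18 RPM in control leaf (SD, n = 3) to 1483 RPM, though with exact mature sequences it stood at -2.63. miR156, which also targets SPL factors, fell by 3.37 ± 0.10, from 486933 ± 23622 to 47184 RPM, and miR444 fell by 3.71 ± 0.12. Adjusted p by edgeR was 5.63e-05 for miR2275, 0.00239 for miR2118, 2.43e-06 for miR529 and 1.19e-05 for miR156.

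Of the 40 families, 33 passed by edgeR in flower, of which 20 rose and 13 fell, and 19 passed the same way under all 4 scalings. Besides miR2275, miR2118 and miR529, the rises among these 19 were miR399 (4.20 ± 0.43), miR166 (2.54 ± 0.05) and miR820 (2.15 ± 0.09), which stood at -2.40 with exact mature sequences. The falls besides miR156 and miR444 were miR1432 (-2.48), miR1425 (-2.23), miR535 (-1.80), miR528 (-1.46), miR408 (-1.37), miR1876 (-1.34), miR172 (-1.09), miR171 (-1.01), tasiR-ARF (-0.53), miR167 (-0.32) and miR398. miR398 had 0 reads in flower, at least 2.41-fold lower than in control leaf. With exact mature sequences tasiR-ARF stood at 1.75 and miR167 at 2.07. Rises of miR319 (2.89), miR1878 (1.84), miR390 (1.70), miR1868 (1.60), miR1850 (1.48), miR164 (1.47), miR168 (1.40) and miR160 (1.17) did not pass under every scaling. Of these, miR1850, miR164, miR168 and miR160 turned negative without a normalization factor.

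**Figure D4:**
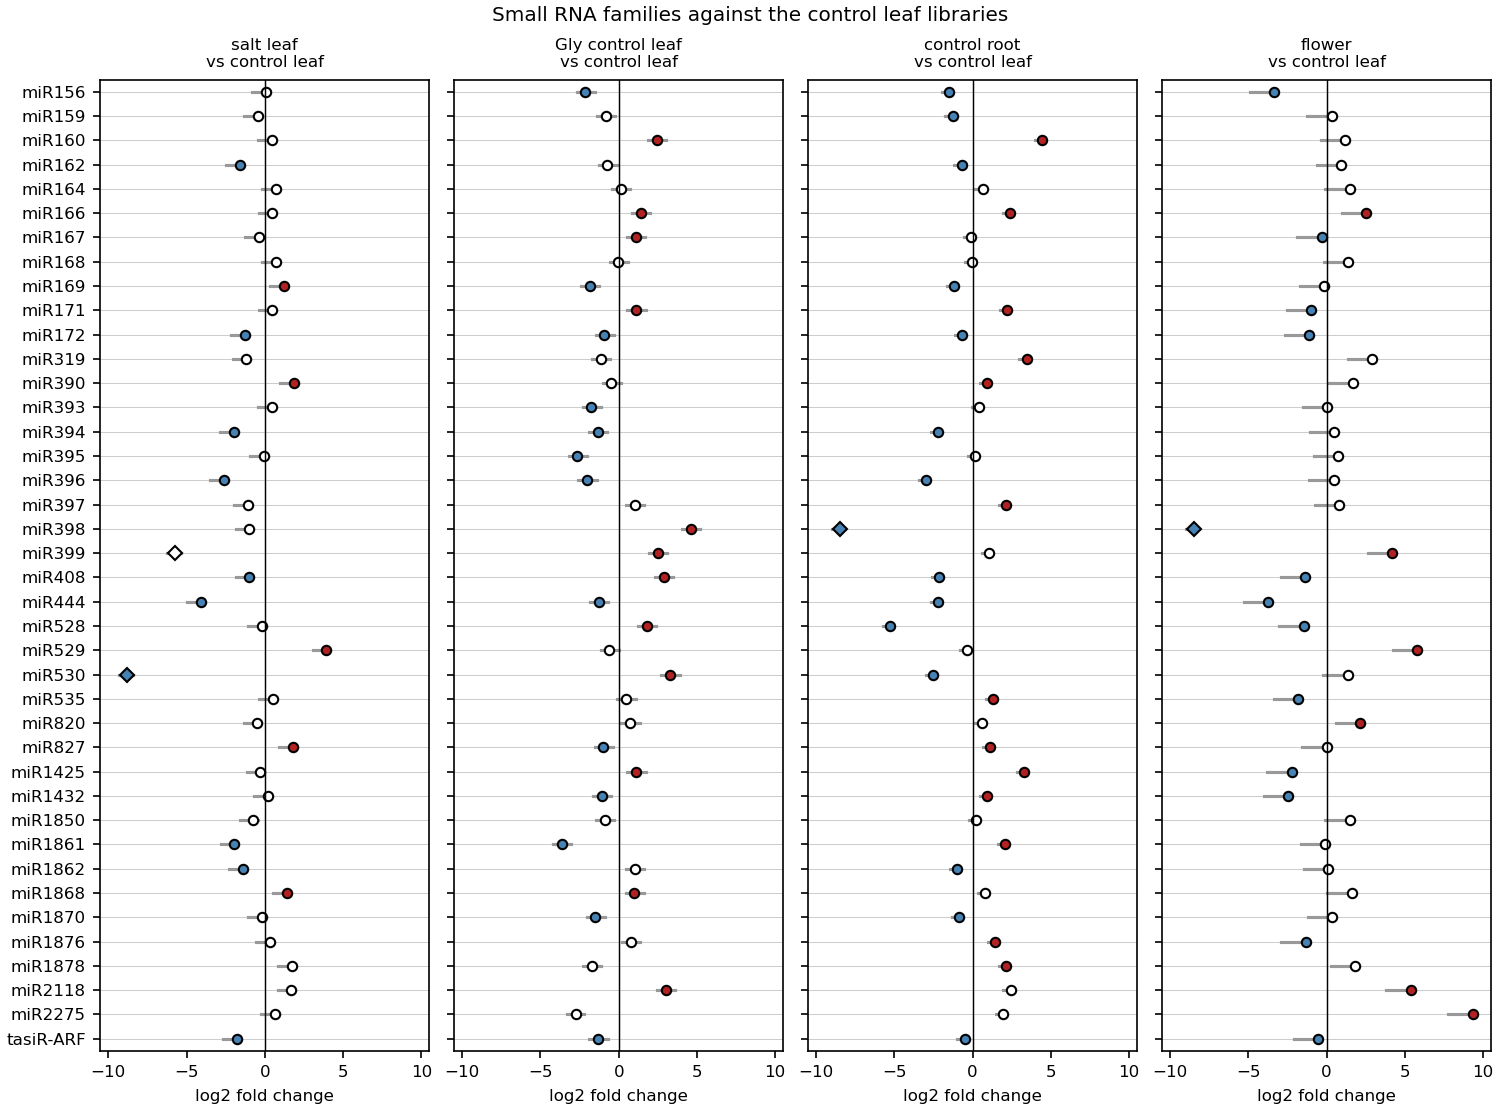
Log2 fold change against control leaf (horizontal axis) of each family in salt leaf, Gly control, control root and flower, 1 panel each, with filled red or blue dots for families that passed the same way under all 4 scalings, white dots for others, grey lines for the span over the scalings and diamonds for fitted values at 0 reads. In flower 6 families are filled red and 13 blue, and miR2275 lies farthest to the right at 9.37.

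Both reproductive triggers rose in flower (2 adjusted over the list alone by edgeR), with a median of 7.38 at percentile 99.5 of random lists. In phase change, miR529 rose and miR156, miR172 and miR535 fell (4 adjusted over the list alone). In copper and laccase, miR398, miR408 and miR528 fell and miR397 did not pass (3 adjusted over the list alone), with a median of -1.32 at percentile 2.90 when miR398 is set to its bound. Of 9 rice or monocot families, 2 rose and 5 fell (7 adjusted over the list alone), with a median of -1.34 at percentile 0.425. In leaf and meristem development, 5 of 6 rose and miR171 fell (6 adjusted over the list alone), but of the rises only that of miR166 held under all 4 scalings. In the salt list, 6 of 14 rose and 5 fell (11 adjusted over the list alone). In auxin, miR160 and miR390 rose and miR167 and tasiR-ARF fell (4 adjusted over the list alone). In nutrient, miR399 rose and miR444 fell (2 adjusted over the list alone). In the machinery list, miR168 and miR162 (0.93) rose (2 adjusted over the list alone), and without a normalization factor they stood at -0.15 and -0.61.

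The split of 20 rises and 13 falls in flower was 12 and 15 with DESeq2 size factors, 6 and 23 without a factor, 8 and 22 without the library labelled salt root, and 10 and 22 with reads of 20 to 24 nt. Without control leaf replicate 1 it was 5 and 19 by edgeR, where of 31 families that could be measured 18 kept their call, 11 lost it, and miR396 (-0.78) and miR1870 (-0.88) passed the other way. Among the 11, miR162 (-0.27) and miR394 (-0.75) also changed sign. The other 9 were miR160, miR164, miR168, miR319, miR390, miR530, miR1850, miR1868 and miR1878. Without replicate 2 the edgeR calls of miR319 (adjusted p 0.0679), miR394 (0.0527), miR530 (0.134) and miR1876 (0.0580) ended, and without replicate 3 those of miR394 (0.0754) and miR1876 (0.0526). The median log2 value was 0.40 with TMM, -0.09 with DESeq2 size factors, -1.15 without a factor, 0.24 without miR156 and -0.83 without replicate 1. Against control leaf replicate 2 alone, which shares the longest read of 35 nt with flower, 9 families were higher and 9 lower past the 2-fold size rule.

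The comparison of the library labelled salt root with control root was planned as the salt effect in root. Since this library holds the sequences of Gly control, which is labelled leaf, the values compare that library with control root. miR398 was at least 76.8-fold higher in the library labelled salt root, with 0 reads in control root. miR528 had a ratio of 137 (95% interval 125 to 151), miR530 of 58.2 (16.1 to 481, 2 reads in control root) and miR408 of 31.9 (23.8 to 43.9). miR1861 was lower, with a ratio of 0.0180 (0.00880 to 0.0338), as was miR160 with 0.248 (0.232 to 0.265).

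Of the 40 families, 6 were higher and 11 lower past the size rule, without a test, in the library labelled salt root. The other higher families were miR1862 (3.97) and miR167 (2.28). The other lower ones were miR1878 (0.0705), miR393 (0.220), miR1425 (0.221), miR827 (0.235), miR1432 (0.246), miR390 (0.386), miR397 (0.467), miR171 (0.482) and miR1850 (0.486). The split was 10 and 6 with DESeq2 size factors and 14 and 4 without a factor, where miR171 and miR1850 stood at log2 ratios of 0.00 and 0.02. Of the 4 copper and laccase families, miR398, miR408 and miR528 were higher and miR397 lower, with a median log2 ratio of 5.63 at percentile 99.8 when miR398 is set to its bound. In the salt list, 4 of 14 were higher and 3 lower, in auxin 1 of 5 higher and 3 lower, and in rice or monocot 3 of 9 higher and 3 lower. In nutrient, miR827 was lower, and in leaf and meristem development miR171 was. Among the 4 phase change families, the 2 machinery families and the 2 reproductive triggers, 0 were past the size rule.

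Of the 37 families with reads in all libraries of the 3 salt comparisons, 0 moved at least 2-fold the same way in salt leaf, Gly salt and the library labelled salt root, each against its own control. The 3 comparisons are not separate, since the library labelled salt root repeats Gly control, the control of Gly salt. In Gly salt none of the 32 families with at least 10 RPM reached 2-fold, so this count was nearly bound to be 0. It says nothing about a shared response to salt.

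Single sequences were tested as well, 90655 of them by edgeR, those of the listed families included. In flower, 17431 of the 35842 sequences of 24 nt passed, and 16116 of these rose, or 92.5%. Of those of 21 nt, 1731 rose and 3169 fell in flower, and of those of 22 nt, 423 and 1219. In salt leaf 1330 of 21 nt rose and 2855 fell. Rises led there at 22 nt, 1328 and 967, and at 24 nt, 1966 and 1655. Sequences qualified by their reads in any library, so those high only in flower or in the deep Gly libraries entered the test. Part of the excess of rises in flower and Gly control can come from this choice, which was not tested. Among all lengths 20192 sequences rose and 8723 fell in flower. In salt leaf 9923 rose and 7236 fell, in Gly control 28061 and 15503, and in control root 13540 and 8315. Without a normalization factor the split was 14855 and 4129 in salt leaf and 40658 and 8798 in Gly control. Among sequences with at least 100 reads in a library it was near even in salt leaf, 3199 and 3071, and in control root, 4106 and 4123, and it was 8826 and 6010 in Gly control and 3709 and 2282 in flower. These calls rest on control leaf replicate 2. Without it 0 passed in salt leaf, 7468 in Gly control (3050 rises and 4418 falls), 1 in control root and 2 in flower by edgeR, against 18290, 32517, 22348 and 27227 at an unadjusted p under 0.05.

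The sequences outside the listed families with the largest rise had 0 reads in control leaf. In salt leaf they were 19, 19 and 25 nt long with 198, 170 and 162 reads, at least 149-fold, 128-fold and 122-fold higher. In Gly control they were 26, 25 and 23 nt long with 22728, 19758 and 14415 reads, at least 2727-fold, 2371-fold and 1730-fold higher. In control root they were 18, 23 and 22 nt long with 11726, 8808 and 5496 reads, at least 12377-fold, 9297-fold and 5801-fold higher. In flower they were 21, 21 and 24 nt long with 804, 790 and 622 reads, at least 568-fold, 558-fold and 440-fold higher. The largest falls in salt leaf and in flower were 3 sequences of 20, 22 and 21 nt that hold adapter sequence. In Gly control 2 of the 3 largest falls were of that kind, and the other, of 24 nt, was at least 771-fold lower. In control root the largest falls were sequences of 21, 21 and 20 nt, at least 203-fold, 144-fold and 140-fold lower.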

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

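All tests in this part were chosen after the results they concern had been seen.

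The salt effect in Gly leaf minus that in leaf passed an interaction test by edgeR for 23 of 40 families, with 25 at an unadjusted p under 0.05, and each of these families was singled out by that difference between groups. On the log2 scale the difference was -3.67 for miR529, -1.71 for miR390, -1.50 for miR1868, -0.96 for miR535, -0.94 for miR827, -0.91 for miR168, -0.88 for miR169 and -0.78 for miR166. It was 0.41 for miR1870, 0.57 for miR159, 0.81 for miR528, 0.86 for miR408, 0.94 for miR1425, 0.94 for miR167 and 1.46 for miR172. It was 1.78 for miR1862, 1.88 for miR397, 2.09 for tasiR-ARF, 2.16 for miR162, 2.22 for miR394, 2.89 for miR396 and 4.23 for miR444. For miR530 the fitted difference was 9.11, which is no bound, since salt leaf had 0 reads. With DESeq2 size factors miR1870 turned to -0.09, and without a normalization factor miR166 turned to 0.09. Left out in turn, control leaf replicate 1 ended the edgeR calls of miR169 (adjusted p 0.0785) and miR1870 (0.0537), replicate 2 those of miR397 (0.0689) and miR530 (0.0579), and replicate 3 that of miR1870 (0.110).

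Other choices ended more of these calls by edgeR. DESeq2 size factors ended those of miR159 (adjusted p 0.798), miR167 (0.0679), miR397 (0.135), miR408 (0.264), miR528 (0.173), miR1425 (0.304) and miR1870 (0.642). Without a normalization factor those of miR166 (0.379), miR168 (0.868), miR169 (0.947), miR535 (0.511) and miR827 (0.762) ended. Scaled without miR156, those of miR159 (0.0718), miR397 (0.0646), miR1425 (0.0629) and miR1870 (0.297) ended, and without single-read sequences that of miR1870 (0.0616). Exact mature sequences ended those of miR168 (0.0838), miR169 (0.220), miR530 (0.507), miR827 (0.0627), tasiR-ARF (0.0815) and miR167 (0.100), which turned to -0.15. All of these values use Gly control, whose sequences are also listed under the label salt root, and hold only if the label Gly control is right. Of the 4 groups in this test 3 have 1 library, so its p-values rest on the spread of the control leaf libraries alone, which may be technical. The longest reads were 27 nt in salt leaf and 33 or 35 nt in control leaf, but 28 nt in both Gly libraries, so read length differed in the non-Gly part of the test alone. With miR172, miR394, miR396, miR444 and tasiR-ARF among the 6 families that also fell in Gly control without salt, the difference cannot be read as a difference in salt effect alone.

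The library labelled salt root held all sequences of Gly control, and 100% of the sequences that Gly control holds once, which is consistent with a repeated or mislabelled file. Small RNA common to separate libraries is argued against, since no other pair of libraries shared more than 17.97% of such sequences. Whether the shared library comes from root or from leaf cannot be told apart. Of the 21 families that passed the test and differed 2-fold between control root and control leaf, 47.6% lay nearer to control root in it, while Gly salt, labelled leaf, stood at 0.740 to 1.80 times its level in the 32 families with at least 10 RPM. An effect of salt in root stays untested.

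The 9 families that passed the test and fell at least 2-fold in salt leaf were weighed as a set, without miR319, miR397 and miR399, which were lower by as much but did not pass. Under each of the 4 scalings 9 of 9 stood below control leaf. In salt leaf the scalings shifted most families nearly alike. The median rose at most from -0.18 with TMM to 0.08 with DESeq2 size factors. Families chosen as 2-fold lower under TMM could hardly turn at such shifts. Scaling or the share of miR156 as the cause is therefore not decided by this count. That the control leaf libraries stand apart from all others by run or plants is a candidate explanation for the falls alone, because 6 of the 9 (miR172, miR394, miR396, miR444, miR1861 and tasiR-ARF) also fell in Gly control, without salt, under every scaling, where independent lists would share 2.93. Part of this excess may come from the shared control libraries, and the rises go against it, since 1 of the 6 that passed and reached 2-fold was shared, against 1.80 for independent lists, and 50.0% of all 40 families had the same sign, within the 42.5 to 72.5% of 1000 simulations with no effect. In control root, miR172, miR394, miR396, miR444 and tasiR-ARF also fell under every scaling, but miR1861 rose (2.09). In flower, miR172, miR444 and tasiR-ARF fell under every scaling, while miR394 and miR396 changed sign and miR1861 did not pass under each. Tissue differs in these comparisons. A response to salt stays open and cannot be told apart from control leaf libraries that stand apart. Of the 9 families, 0 were lower in Gly salt than in Gly control with an interval below 1, but Gly lines can respond otherwise.

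Sequences of 6 listed animal miRNAs reached 196 RPM in control root, above the 28.7 to 37.4 RPM of the control leaf libraries, in reads outside the listed rice families. Rice sequences that share a core with an animal miRNA and RNA of an animal in the library cannot be told apart as the source. Gly salt, a deeper library, held the sequences at 0.0497% of that level and salt leaf at 3.04%, but control leaf held them at 17.1%, so rice leaf neither held them throughout nor lacked them throughout. Of the 6 listed, 3 reached 1 RPM in control root, let-7a with 166, miR-143 with 17.5 and miR-21 with 10.7. The mix differed between libraries. In control leaf replicates 1 to 3, miR-122 had 19, 17 and 29 reads against 2 in control root, while miR-143 had 4, 1 and 4 against 69. Gly salt held 2 reads of let-7a and none of the others. These values argue against rice sequences read at a like level in all leaf, but they do not identify the source.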

How the results depend on the processing

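The alternatives without the library labelled salt root, scaled without miR156, with control leaf libraries summed and with control leaf replicate 2 alone were chosen after the data had been seen, as were all settings of the interaction test. Of 2373 values of single families under an alternative, 2135 kept their direction and their side of the threshold, 117 lost the call, 63 gained it and 58 reversed. For the values below the cause was not tested, except where fewer reads, families or libraries enter by construction. No paired analysis was possible because the labels give no shared replicate numbers and each group other than control leaf has 1 library. Shares of genome-matched reads were not run, since no genome was used. With 2 control leaf libraries each lone library is still assumed to vary like them.

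With each control leaf library left out, families past the edgeR test numbered 22 to 24 in salt leaf, 31 to 37 in Gly control, 29 to 31 in control root and 24 to 29 in flower, and 21 to 25 in the interaction test. Sequences past the test numbered 0 to 16932, 7468 to 38674, 1 to 21691 and 2 to 28341 in the same order of comparisons. The control leaf share of 21 nt ranged from 47.6 to 47.7% and that of 24 nt stayed at 14.1%. With the control leaf libraries summed and the 2-fold size rule, 12 families passed in salt leaf, 21 in Gly control, 18 in control root and 19 in flower. With control leaf replicate 2 alone the counts were 13, 20, 18 and 18. Sequences with at least 100 reads gave 6270, 14836, 8229 and 5991 calls, from fewer sequences tested. For the library labelled salt root, 8 families passed at 100 RPM and 11 at 4-fold. For Gly salt against Gly control, 2 passed with 20 to 24 nt.

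Counted over distinct sequences, over all lengths and without miRNA families, the 21-nt share was 8.95, 26.1 and 14.2% in Gly control, 8.86, 27.1 and 14.4% in Gly salt, and 8.67, 14.0 and 11.2% in flower. It was 9.81, 27.1 and 16.0% in salt leaf, 9.00, 25.3 and 14.2% in the library labelled salt root, 14.8, 15.7 and 16.5% in control root, and 16.3, 44.5 and 26.2% in control leaf. The 24-nt share was 56.3, 18.6 and 29.7% in Gly control, 59.4, 22.4 and 35.1% in Gly salt, and 61.7, 54.4 and 63.5% in flower. It was 50.6, 21.4 and 34.2% in salt leaf, 56.1, 18.1 and 29.6% in the library labelled salt root, 29.3, 11.0 and 18.8% in control root, and 48.1, 13.2 and 33.9% in control leaf.

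Reversed log2 values without a normalization factor in salt leaf were -0.18 for miR168, -0.18 for miR164, -0.34 for miR535, -0.39 for miR171, -0.40 for miR166, -0.82 for miR156 and -0.69 for miR1432. In Gly control they were 0.13 for miR390, 0.0055 for miR529 and 0.59 for miR168. In flower they were -0.068 for miR1850, -0.076 for miR164, -1.10 for miR396, -0.38 for miR160, -1.24 for miR159, -1.55 for miR827, -0.15 for miR168 and -0.61 for miR162. In the library labelled salt root against control root they were 0.00387 for miR171, 0.017 for miR1850 and 1.03 for miR162. In Gly salt against salt leaf they were 0.00498 for miR393, 0.40 for miR1870, 1.47 for miR164 and 1.26 for miR159. With DESeq2 size factors miR168 stood at 0.26 in Gly control, and miR396, miR159 and miR827 at -0.051, -0.16 and -0.49 in flower. Scaled without miR156, miR535 and miR164 stood at -0.084 and -0.42 in Gly control.

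With exact mature sequences, reversed values in salt leaf were -0.089 for miR171, -0.00299 for miR166, 0.69 for miR167 and -0.47 for miR1432, and -1.17 for miR820 in Gly control. In control root they were 1.83 for miR167, 0.66 for miR529 and -0.056 for miR820. In flower they were -2.63 for miR529, -2.40 for miR820, 1.75 for tasiR-ARF, 2.07 for miR167, -0.49 for miR159 and -0.33 for miR827. In the library labelled salt root miR820 stood at -1.10. With 20 to 24 nt, flower values were -0.63 for miR396, -0.79 for miR159, -1.10 for miR827 and -0.19 for miR162. Without the library labelled salt root they were -0.77 for miR396, -0.040 for miR160, -0.88 for miR159, -1.21 for miR827 and -0.28 for miR162. Over the control leaf libraries left out in turn, flower values ranged from -0.78 to 0.45 for miR396, from -1.25 to 0.019 for miR827 and from -0.27 to 0.97 for miR162, the lowest each time without replicate 1.

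On the TMM scale, 3 counts came to 1.27 RPM in flower and 0.963 in control root, where miR398 had 0 reads, and to 1.16 RPM in salt leaf, where miR399 and miR530 had 0. Lower levels were not detectable there.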

Other observations

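The tests in this part were chosen after the data had been seen. miR156, which targets SPL factors, was read mainly in forms of 20 and 21 nt. The 21-nt forms made up 61.3% ± 0.184 of both in control leaf (SD, n = 3), 49.4% in salt leaf, 49.0% in Gly control and 50.9% in Gly salt. The share was 31.1% in control root and 41.4% in flower. The differences from control leaf exceeded the range of its libraries, 61.1 to 61.5%. The first base of 21-nt reads was T in 86.8% ± 0.251 in control leaf (SD, n = 3), 72.0% in salt leaf, 74.7% in Gly control, 76.5% in Gly salt, 56.5% in control root and 55.0% in flower. The 21-nt form of miR156 begins with T. It made up 1785595 of 2693023 reads of 21 nt in control leaf replicate 1, 629527 of 1257348 in salt leaf and 45216 of 974594 in flower. The T share thus rests in part on this form, and shares without it were not computed. The first base of 24-nt reads was A, the base favoured by the ARGONAUTE proteins that guide DNA methylation, in 60.6% ± 0.889 in control leaf (SD, n = 3), 56.6% in salt leaf, 54.1% in Gly control, 57.6% in Gly salt, 51.2% in control root and 50.0% in flower.

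miR2275, a trigger of reproductive phased siRNAs, was near the detection limit in the other groups with 1 library. It had 1 read in salt leaf, 1 in Gly control, 2 in Gly salt and 3 in control root, against 389 in flower. miR2118, also such a trigger, had 1, 33, 20 and 2 reads in the same libraries, against 12 in flower. Without further scaling it stood at 1.59 RPM in Gly control and 0.971 in Gly salt, near the 1.89 in flower. On the TMM scale these values were 0.964, 0.587 and 5.08 RPM. How far miR2118 in flower exceeded the Gly libraries thus depends on the scaling. Listed dicot miRNAs that rice lacks summed to between 0.0475 RPM in the library labelled salt root and 3.89 RPM in salt leaf.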
